A study of Mus musculus with 2 samples.

How the data were processed

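Total RNA of whole bone marrow, not sorted by cell type, was taken from 1 P95H mouse and 1 WT mouse on a C57BL/6 background, depleted of ribosomal RNA, made into stranded libraries with 9 cycles of PCR, and sequenced together in a single NextSeq500 run as 75 bp paired reads, per the labels' protocols. The submitters' processing notes name Trim Galore, cutadapt, STAR 2.5.3a, Picard 1.96, featureCounts, edgeR and the mouse build mm9, without saying what each was used for. Whether counting used strand and how reads with several positions were treated is not given in the sources used here, so overlapping, antisense and near-identical genes are uncertain.

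The table holds 12860 genes by Entrez number and symbol, 164 of them with no symbol. Raw read counts per gene and library are as the authors deposited them, per the file headers. The authors also deposited CPM, a normalised signal whose columns sum to 1067265 in the P95H library and 934268 in the WT library rather than to a common total. Dividing counts by these values gives effective library sizes of 39696495 and 47880724 reads, 0.937 and 1.07 times the listed totals. Every gene had a CPM above 1 in at least 1 library. The authors' deposited mean column equals the mean of both CPM columns, and their log2 fold change and fold columns equal the CPM ratio with 0.001 added to each value. These columns were checked against the counts and CPM and not used further.

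The groups came from the genotype label, with 1 library per genotype. No p-value was computed, because 1 library per group gives no estimate of the spread between mice. Differences were taken on log2(CPM + 1) from the deposited CPM, and a gene was called at least 2-fold higher or lower at a difference of 1 or more in size. Ratios of CPM have exact conditional binomial (Clopper-Pearson) intervals at a 95% level, and shares of counts have exact binomial intervals. The reads carry no molecular identifiers here, so intervals and floors cover counting error only. Where a library had 0 counts, a bound was computed with that library at a floor of 3 counts, a less strict limit than the upper end of the interval, 0.0756 CPM in the P95H library and 0.0627 CPM in the WT library.

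For this work, 42 gene lists were fixed before the data were examined, covering bone marrow cell types, splicing, cell division, metabolism, stress responses, sex-linked genes and technical classes. The median difference of each list with at least 5 measured genes outside the sex lists was ranked among 10000 random lists of the same size, drawn without replacement within 20 bins of mean expression. A list stands apart below the 2.5th or above the 97.5th percentile, which describes these libraries and is no test of genotype. Of 39 ranked lists, 7 stood apart higher and 18 lower. By chance 1.95 would lie outside if the genes of a list varied independently, as randomly drawn genes do. Markers of a cell type can vary together, so more lists can lie outside without any effect of genotype. Lists of cell type markers were read as transcript levels, not as cell numbers. The mitochondrial list matched 0 of 15 genes under the symbols it was written with, and was matched by the names the table uses after the data were seen.

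Genes are named by a rule fixed beforehand. It takes Srsf2, Ezh2 and the genes of the sex lists. It also takes the 10 largest positive and 10 largest negative differences among genes with a CPM of at least 10 in a library, leaving out the sex lists, immunoglobulin and T cell receptor variable, diversity and joining segments, and predicted, clone and small RNA names. From each list that stands apart it takes up to 4 genes with the largest absolute difference, and from other lists at most 2. Other genes are said to be chosen after their values were seen. Some genes that the rule takes are not reported here.

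Alternatives fixed beforehand were pseudocounts of 0.1 and 5, centring on the median or on a trimmed mean, totals without haemoglobin and the 20 most abundant genes of either library, no filter, a CPM of at least 10 in 1 library or of at least 1 in both, 1.5-fold and 4-fold sizes, unmatched random lists, 50 bins, means in place of medians, lists without genes shared with another family, and random lists without predicted genes. Plain totals, a counting interval wholly beyond 2-fold, and 20 further sets of random lists for the megakaryocyte list were added after seeing the data. Gene order came from a RefSeq table of GRCm38.p6, which matched 12531 of the Entrez numbers (97.4%). That build differs from the one the submitters name, so it was used only for which genes neighbour each other.

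The steps were tested on simulated data of the P95H against WT comparison with counting noise only over 12860 genes. The size rule called 0 of 50 genes made 1.5-fold different, 50 of 50 at 3-fold, 50 of 50 at 4-fold, 50 of 50 at 8-fold, and 0 of 12660 unchanged genes. The intervals held the true ratio for 95.1% of genes. Of 200 random lists of 20 genes, 12 stood apart, and all 100 lists shifted by 0.3 did. This simulation has no variation between mice and no spread of differences among its unchanged genes, so a shift of 0.3 shows more readily there. In the data, the middle 95% of random lists reached 0.39 for the secondary and tertiary granule list. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.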

Results

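RNA of whole bone marrow was sequenced from 1 mouse carrying the Srsf2 P95H change on 1 allele and from 1 Srsf2 WT mouse, giving 2 libraries in 2 groups. Srsf2 encodes a splicing factor of the serine and arginine rich (SR) family, and the P95H substitution occurs in human myeloid neoplasms. The comparison addresses what expression of the mutant protein from its own locus, switched on by tamoxifen through a Cre recombinase at the Rosa26 locus, does to bone marrow transcripts. Per the sample titles, the WT mouse also carried this Cre recombinase, and both mice were treated with tamoxifen in vivo. The P95H mouse was a female of 14 weeks and the WT mouse a male of 12 weeks, so genotype, sex, age and individual cannot be separated, and no difference below has a replicate check. The listed genes held 42366695 counts in the P95H library and 44733445 in the WT library. Intervals in brackets are 95% counting intervals of the ratio of CPM (read counts divided by the scaled library size), P95H over WT, and cover counting error only. Differences are P95H minus WT on the log2(CPM + 1) scale, which understates the difference of low genes.

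Srsf2 (Entrez 20382) had 9162 counts in the P95H library and 10767 in the WT library, 231 against 225 CPM, a ratio of 1.03 (0.998 to 1.06) and a difference of 0.04, which was -0.15 with plain totals and -0.10 with totals without haemoglobin and the most abundant genes. The gene is edited in place, so its level checks no label. The sex-linked genes went with the labels. Xist, the RNA that coats the inactive X chromosome, had 16907 counts in the P95H library and 23 in the WT library. Of the Y-linked genes, Ddx3y had 0 counts against 6303, Uty 0 against 1281, Kdm5d 0 against 915 and Eif2s3y 1 against 3376. With the P95H level set at the floor of 3 counts, Ddx3y was 1742-fold lower, Uty 354-fold and Kdm5d 253-fold. By the counting interval Ddx3y was at least 1416-fold lower, Uty at least 287-fold and Kdm5d at least 205-fold. Of the other 7 listed genes of X inactivation or escape from it, Kdm5c, Kdm6a, Eif2s3x, Ddx3x, Jpx and 5530601H04Rik lay between 0.17 (Jpx) and 0.60 (Eif2s3x), and Ftx was at -0.43.

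Across 12860 genes, 226 were at least 2-fold higher in the P95H library and 270 at least 2-fold lower, while 12364 (96.1%) lay between. By the difference on the log2(CPM + 1) scale, which orders genes otherwise than their ratios do, the 10 highest genes included Hmgn2-ps1, a processed copy of Hmgn2 (641 counts against 28, ratio 27.6, 18.9 to 41.9), the glutathione-cleaving enzyme Ggt1 (1015 against 98, ratio 12.5, 10.1 to 15.5) and Erfe, the erythroblast hormone that lowers hepcidin (829 against 81, ratio 12.3, 9.82 to 15.7). The extracellular proteoglycan gene Vcan had 5525 counts against 869, the transglutaminase gene Tgm1 923 against 119, and the interferon-induced oligoadenylate synthetase genes Oas1g and Oas2 had 419 against 33 (ratio 15.3, 10.7 to 22.5) and 2182 against 376. The stefin genes BC117090, Stfa2 and BC100530 had ratios of 9.85, 7.53 and 6.65. On the lower side the non-coding RNA gene BC018473 had 0 counts against 11077 (3061-fold lower at the floor, at least 2489-fold by the interval). Rprl2 and Rprl3, copies related to the RNA of ribonuclease P, had 0 against 2199 counts (608-fold lower at the floor, at least 494-fold by the interval) and 1 against 5230 (ratio 0.000231, 5.84e-06 to 0.00129). The eosinophil ribonuclease genes Ear12 and Ear10 had 4 counts against 2432 and 5 against 1412. The other 5 of the 10 lowest were Cxcr5, Fcmr, Fcer2a, Ighd and Ccr7, which are genes of B cells or, for Ccr7, of lymphocytes and dendritic cells, with ratios from 0.143 (Cxcr5) to 0.192 (Ccr7). Hmgn2-ps1, the Oas1, stefin, Ear and Rprl genes have near-identical copies, so counting could have split their reads, and sequence differences between the mice were not analysed here. Genes left out of this ranking as predicted or clone names numbered 782, of which 22 were at least 2-fold higher and 8 lower, and 138 immunoglobulin or T cell receptor segments held 10 higher and 16 lower. The counts of higher and lower genes depend on the scaling: from plain totals of listed counts, an alternative chosen after seeing the data, 134 were higher and 463 lower, so that the share of higher genes was 22.4% in place of 45.6%, and from totals without haemoglobin and the most abundant genes 178 and 477 (27.2%).

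**Figure D1:**
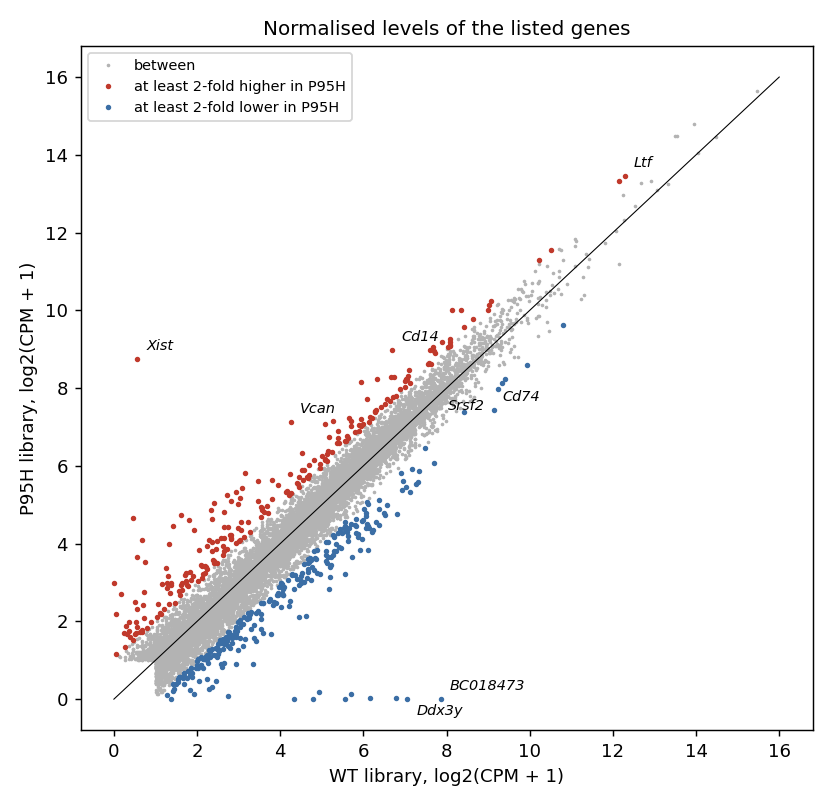
Normalised levels of the 12860 listed genes, as log2(CPM + 1), in the WT library (horizontal) and the P95H library (vertical); each point is a gene and the line marks equal levels. The 226 red genes are at least 2-fold higher and the 270 blue genes at least 2-fold lower in the P95H library; Xist (16907 counts against 23) and Ddx3y (0 against 6303) lie far from the line, as does BC018473 (0 against 11077).

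Transcripts of neutrophils were higher in the P95H library. Of 21 measured genes of the mature neutrophil list, 11 were at least 2-fold higher, 0 at least 2-fold lower and 10 between, with a median difference of 1.11 against a middle 95% of -0.07 to 0.33 for random lists of the same size and expression (percentile 100). Stfa2 was at 2.65, BC100530 at 2.53, the Schlafen gene Slfn4 at 1.88 (40867 counts against 13313) and Ifitm6 at 1.64. The list of secondary and tertiary granule proteins had a median of 0.89 (percentile 100), with 4 of 18 genes at least 2-fold higher and 14 between. These 4 were the iron-binding proteins of neutrophil granules Lcn2 (404507 counts against 217193, ratio 2.25, 2.23 to 2.26) and Ltf (443525 against 239533, ratio 2.23, 2.22 to 2.24), AA467197 (1821 against 962) and Cd177 (118555 against 69608). Primary granule genes, made earlier in neutrophil development, had a median of 0.48 (percentile 98.9), with all 8 between. Ctsg was at 0.69, Prtn3 at 0.67, Ms4a3 at 0.59 and Elane at 0.55. The secondary and tertiary granule list took 6.67% of all counts in the P95H library (exact interval 6.66 to 6.67) and 3.94% in the WT library (3.94 to 3.95), and the mature neutrophil list 5.77% (5.77 to 5.78) and 3.49% (3.49 to 3.5).

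Lists of other myeloid cells were lower or did not stand apart. The eosinophil list had a median of -0.92 (percentile 0), with 4 of 10 genes at least 2-fold lower and 6 between. Ear10 was at -4.76, the interleukin 5 receptor gene Il5ra at -1.33 (296 counts against 970), Ear2 at -1.25 and Ear6 at -1.17. The basophil and mast cell list had a median of -0.58 (percentile 0.02) with 8 of 9 genes between. Histidine decarboxylase (Hdc), which neutrophil precursors also express, was 2.24-fold higher (2.19 to 2.28), while Gata2 was at -0.87, Ms4a2 at -0.83 and Mcpt8 at -0.75. The dendritic cell list had a median of -0.70 (percentile 0), with 5 of 13 genes at least 2-fold lower. The MHC class II genes H2-Aa, H2-Eb1 and H2-Ab1, which B cells express too, had ratios of 0.283, 0.281 and 0.299, and the plasmacytoid dendritic cell gene Siglech 0.422. The monocyte and macrophage list, with a median of 0.21 (percentile 95.2), did not stand apart by the rule. Its members diverged, with Cd14, a co-receptor for bacterial lipopolysaccharide, at 20131 counts against 4884 (ratio 4.97, 4.82 to 5.13) and Cd74, the invariant chain of MHC class II, at 6826 against 26854 (ratio 0.307, 0.299 to 0.315). The Cd74 ratio lay near those of the class II genes above, which B cells express too, so it need not come from monocytes. The marrow was not sorted, so the cells behind the Cd14 difference are not known either.

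Transcripts of B cells, natural killer cells and T cells were lower. Of 22 mature B cell genes, 19 were at least 2-fold lower, 0 at least 2-fold higher and 3 between, with a median of -1.78 (percentile 0; random lists -0.13 to 0.16). The chemokine receptor gene Cxcr5 had 135 counts against 1136 (ratio 0.143, 0.119 to 0.171), the IgM receptor gene Fcmr 329 against 2223, the low-affinity IgE receptor gene Fcer2a 132 against 993, and Ighd, the constant region of IgD, 245 against 1677. The pro-B and pre-B cell list had a median of -1.26 (percentile 0), with 16 of 24 genes at least 2-fold lower and 8 between. The B cell receptor signalling chains Cd79a and Cd79b were at -1.76 and -1.75, the B lineage transcription factor Pax5 at -1.63 and Vpreb3 at -1.62. Of 15 natural killer cell genes, 9 were at least 2-fold lower and 6 between, with a median of -1.09 (percentile 0). Perforin (Prf1) had 31 counts against 240, Eomes 34 against 236, granzyme A (Gzma) 62 against 272 and the receptor gene Klra8 12 against 105. The T cell list had a median of -0.45 (percentile 0.1), and was not compared with the B and natural killer cell lists. In this list 3 of 23 genes were at least 2-fold lower, Ccr7 (524 counts against 3286), Tcf7 (105 against 342) and Trbc1 (14 against 92), and 20 lay between, among them Cd8b1 at -0.83. All 23 lay below 0. Ccr7 is a gene of lymphocytes and dendritic cells, so its difference need not come from T cells. The plasma cell list did not stand apart (median 0.18, percentile 94.5), although Irf4 (ratio 0.320) and Mzb1 (0.427) were lower. Of its 16 genes, 10 lay above 0. Its percentile was 98.9 with a CPM of at least 10 in 1 library and 32.5 with means over members. The mature B cell list took 0.140% of counts in the P95H library (0.139 to 0.141) and 0.296% in the WT library (0.294 to 0.297).

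**Figure D2:**
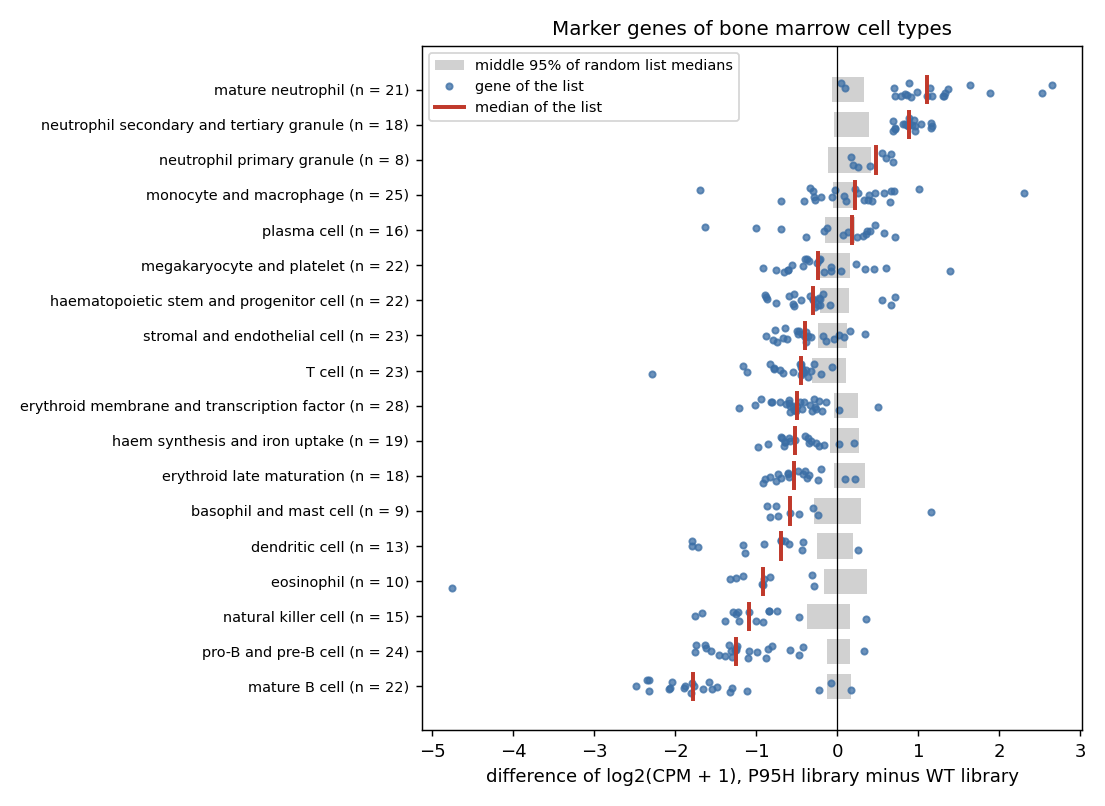
Differences of log2(CPM + 1), P95H library minus WT library, for the genes of each cell type list (points; n is the number of genes, not of libraries), with the list median (red line) and the middle 95% of the medians of 10000 random lists of the same size and expression (grey). Medians run from -1.78 for mature B cell genes to 1.11 for mature neutrophil genes.

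Erythroid transcripts were lower, and few members of the ranked lists passed 2-fold. The late maturation list had a median of -0.54 (percentile 0; 18 of 18 genes between), the haem synthesis and iron uptake list -0.52 (percentile 0; 19 of 19 between) and the membrane and transcription factor list -0.50 (percentile 0; 2 of 28 at least 2-fold lower, 26 between). The 2 genes past 2-fold were Bpgm, which makes the red cell metabolite 2,3-bisphosphoglycerate (11032 counts against 30884), and carbonic anhydrase 1 (Car1, 3462 against 8482). Aqp1 was at -0.94 and Xpo7 at -0.82. Alas2, the first enzyme of haem synthesis in erythroid cells, had a ratio of 0.504 (0.497 to 0.512), with Uros at -0.85, Slc11a2 at -0.70 and Abcb10 at -0.69. Fam46c, Mkrn1 and Ube2l6 of the late list lay from -0.92 (Fam46c) to -0.83 (Ube2l6). The 4 measured haemoglobin genes, too few for a percentile, took 0.472% of counts in the P95H library (0.470 to 0.474) and 1.06% in the WT library (1.06 to 1.06), and Hba-a2 and Hba-a1 were at -1.17 and -0.95. The stromal and endothelial list had a median of -0.40 (percentile 0.02; 23 of 23 between), with the endothelial cadherin Cdh5 at -0.88, the niche chemokine Cxcl12 at -0.80, Ebf3 at -0.77 and Pdgfra at -0.74. The stem and progenitor list had a median of -0.31 (percentile 0.17; 22 of 22 between), with Angpt1 at -0.89, Sox4 at -0.88 and Gata2 at -0.87. The megakaryocyte list had a median of -0.24 (percentile 1.7; 1 of 22 at least 2-fold higher, 21 between), and its percentile lay inside the middle 95% under 3 alternatives and at the limit (2.52) under a further one. P-selectin (Selp) was 2.98-fold higher (2.54 to 3.51), while Pf4 was at -0.92 and Ppbp at -0.66.

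Genes induced by interferon were higher in the P95H library. Of 33 measured, 7 were at least 2-fold higher, 0 at least 2-fold lower and 26 between, with a median of 0.60 (percentile 100; random lists -0.13 to 0.12). Oas2 had a ratio of 7.0 (6.27 to 7.83), Rtp4 5.08 (4.43 to 5.85), Oas1a 4.51 (3.99 to 5.10) and Oasl2 3.75 (3.43 to 4.11). The MHC class I list had a median of 0.29 (percentile 98.3, and inside the middle 95% at 90.5 with means over members; 13 of 13 between) and held both H2-D1 at 0.57 and H2-Q6 at -0.62, with the peptide transporter genes Tap1 and Tap2 at 0.55 and 0.43. The heat shock and unfolded protein list did not stand apart (median 0.23, percentile 95.01), with Hspa1b at 1.01 and Asns at 0.96. Neither did the NF-kB and cytokine list (median 0.05, percentile 51.5), which held Clec4e at 1.35 and Ccl4 at -1.07, nor p53 targets (median 0.03, percentile 60.8), with Perp at -0.76 and Mdm2 at 0.63. Immediate early genes had a median of -0.16 (percentile 0.01; 1 of 23 at least 2-fold lower, 22 between), with Nr4a2 at -1.15, Dusp2 and Egr3 both at -0.94 and Klf6 at 0.58.

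Genes of glycolysis and of cholesterol synthesis were also higher. The glycolysis list had a median of 0.60 (percentile 100), with 2 of 21 genes at least 2-fold higher and 19 between. The glucose transporter genes Slc2a1 and Slc2a3 had ratios of 2.36 (2.16 to 2.57) and 1.86 (1.82 to 1.90), the lactate transporter gene Slc16a3 2.03 (1.99 to 2.08) and enolase (Eno1) 1.77 (1.73 to 1.81). The cholesterol list had a median of 0.37 (percentile 100; 22 of 22 between), with Msmo1 at 0.84, Mvd at 0.67 and Fdps at 0.55. Nuclear-encoded oxidative phosphorylation genes did not stand apart (median 0.05, percentile 44.5), with Atp5j at 0.34 and Ndufa1 at 0.32, and neither did mitochondrially encoded genes (median 0.04, percentile 41.6), with ND4L at 0.53 and ND3 at 0.42. Cytosolic ribosomal protein genes had a median of -0.09 (percentile 0; 55 of 55 between), where random lists of equal expression lay between 0.03 and 0.25. Rpl34 was at -0.59, Rps27 at -0.46, Rps9 at 0.29 and Rps28 at -0.23.

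Genes of the splicing machinery did not stand apart. The median was -0.03 for SR proteins (15 genes, percentile 8.21), 0.07 for the core spliceosome and splicing kinases (38 genes, percentile 54.4) and 0.02 for hnRNP proteins (23 genes, percentile 14.8), and 0 of these genes was at least 2-fold higher or lower. Srsf10 was at -0.32, Srsf5 at 0.22, Zrsr2 at 0.28, Snrpd3 at 0.26, Hnrnph3 at -0.41 and Hnrnpa2b1 at 0.33. The nonsense-mediated decay list had a median of 0.08 (percentile 53.8). Smg9 was at 0.48, and Atf4, a transcription factor gene rather than a decay factor, at 0.52. Of 20 genes reported as splicing targets of mutant SRSF2, 0 passed 2-fold and the median was 0.07 (percentile 46.8). Ezh2, a histone methyltransferase gene in that list, had 3784 counts against 5918 (ratio 0.771, 0.740 to 0.803), with Csf3r at 0.86 and Bcor at -0.60. Gene totals say nothing of isoforms, which were not analysed here. Among 34 myeloid neoplasm driver genes the median was 0.03 (percentile 26.1, but 1.97 with means over members). Setbp1 at -1.21 was the single gene past 2-fold, with Gata2 at -0.87. Abundant non-coding RNAs had a median of 0.09 (percentile 55.3), with Neat1 at 0.51 and Rpph1 at 0.41. The medians of the lists in this paragraph other than SR proteins, and those of oxidative phosphorylation, mitochondrially encoded, NF-kB and p53 genes, lay below 0 with plain totals, which moved the median of all genes by -0.17, and with totals without haemoglobin and the most abundant genes, which moved it by -0.13.

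Transcripts of dividing cells were slightly lower. The proliferation list had a median of -0.07 (percentile 0.76; 24 of 24 between), with Cdc6 at -0.29, Cenpe at -0.15, Bub1 at -0.14 and Cenpf at -0.13. DNA replication genes had a median of -0.09 (percentile 0.95; 25 of 25 between), with Gins3 at -0.38, Tk1 at -0.25, Mcm2 at -0.23 and Gins2 at -0.19. Replication-dependent histone genes had a median of -0.20 (percentile 0; 36 of 36 between), with Hist1h1a at -0.55, Hist1h3d at -0.50, Hist1h1b at -0.44 and Hist2h2aa1 at 0.39. The call on the first 2 of these lists, and on ribosomal protein and immediate early genes, rests on matching for expression.

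In the gene order of GRCm38, BC018473 lies among 4 consecutive listed genes that were all lower, near Srsf2 on chromosome 11. These genes were chosen after their values were seen. St6galnac2 and St6galnac1, sialyltransferase genes, had 15 counts against 215 and 2 against 275, and the predicted gene Gm11735 had 0 against 77. The next listed genes toward Srsf2 were Mxra7 (19 against 49, ratio 0.468, 0.260 to 0.809), Jmjd6 (2530 against 2378) and Mettl23 (415 against 486), and Mfsd11 on the far side had 341 against 358. Away from Srsf2 the run was followed by 1810032O08Rik (128 against 181, ratio 0.853, 0.675 to 1.08) and Cygb (30 against 69, ratio 0.524, 0.330 to 0.816). Beyond these, Rhbdf2 had a ratio of 1.46 (1.38 to 1.55) and Ube2o of 0.656 (0.636 to 0.677).

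**Figure D3:**
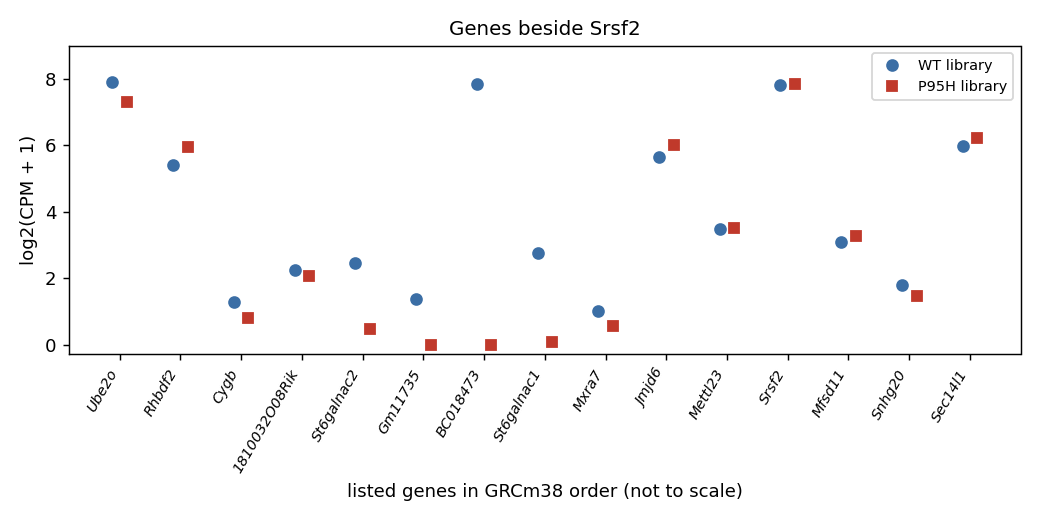
Levels as log2(CPM + 1) of 15 consecutive listed genes around BC018473 and Srsf2 in the WT library (circles) and the P95H library (squares), in GRCm38 order and not to scale. St6galnac2, Gm11735, BC018473 and St6galnac1 have 17 counts in all in the P95H library and 11644 in the WT library, while Srsf2 has 9162 and 10767.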

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

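The plain totals, the interval rule and the 20 further sets of random lists were chosen after seeing the data; the other alternatives were fixed before. Of 25 lists that stood apart, 19 did so on the same side under each setting that gave them a value. Centring moves all genes alike and dropping the filter added no gene, so these settings could not change a rank. Other totals move genes nearly alike and hardly test a rank. The T cell and natural killer cell lists, both among the 19, had under 5 genes with a CPM of at least 10 and were not ranked there. The megakaryocyte list left its tail with a pseudocount of 5 (-0.1323), a CPM of at least 10 (-0.0856), means over members (-0.165) and without genes shared with another family (-0.2285). The last was at percentile 2.52, and 19 of 20 further sets of random lists put it below 2.5, so that call rests on the draw. Without matching on expression, proliferation (-0.072), DNA replication (-0.0939), immediate early (-0.1594) and ribosomal protein genes (-0.0934) no longer stood apart, while monocyte (0.2136) and heat shock genes (0.2279) did; matching changes the random lists, not these medians. With means, MHC class I genes (0.2119) no longer stood apart, and heat shock (0.3133) and myeloid driver genes (-0.0635) did, and with a CPM of at least 10 plasma cell genes did (0.3482). The cause was not tested for these. Genes higher and lower numbered 367 and 593 with a pseudocount of 0.1, 125 and 107 with 5, 134 and 463 with plain totals, 906 and 1039 at 1.5-fold and 31 and 24 at 4-fold. The lower genes numbered 477 with totals without haemoglobin and the most abundant genes, and 154, against 163 higher, with a CPM of at least 10, a filter that removes genes and turns which side holds more. Requiring also an interval wholly beyond 2-fold left 198 and 243. Srsf2 was at -0.1538 with plain totals and -0.1012 without haemoglobin and the most abundant genes, against 0.04, so the direction of its small difference rests on the scaling. Dropping the filter on low values added no gene. The haemoglobin list had too few genes to rank under any setting. No paired analysis was possible because each genotype has 1 library. Depth limits low genes most: with 3 counts as floor, a ratio can be bounded only for genes well above that floor in the other library, and no depth replaces further mice.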

Other observations

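All tests in this part were chosen after the results were seen. Genes were grouped by the letters that open their symbols, giving 192 groups of at least 8 genes, of which 16 stood apart higher and 23 lower. By chance 4.8 each would if the genes of a group varied independently, and genes of a family can vary together. The lowest median was that of the Gimap genes, GTPases of lymphocytes, at -1.18, with 5 of 9 at least 2-fold lower and 9 of 9 below 0. Gimap6 had 669 counts against 2749 and Gimap4 274 against 1036. The Klra genes, receptors of natural killer cells, had a median of -0.81, with 3 of 8 at least 2-fold lower, but Klra17 had 538 counts against 270. In the H2 genes of the MHC (median -0.49), 7 of 23 were at least 2-fold lower and 0 higher. The lowest were H2-Ob (311 against 1699), H2-Aa (1543 against 6574) and H2-Eb1 (1009 against 4325), while H2-D1 was at 0.57.

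On the higher side the Schlafen (Slfn) genes had a median of 0.69, with 3 of 9 at least 2-fold higher, Slfn4 (40867 counts against 13313), Slfn1 (11902 against 6195) and Slfn2 (11074 against 6623), while Slfn14 was at -0.69. The Toll-like receptor (Tlr) genes had a median of 0.51, with Tlr4 at 1.08, Tlr6 at 1.06 and Tlr9 at -0.58. The annexin (Anxa) genes had a median of 0.55, with Anxa1 at 1.07 and Anxa6 at -0.48. Of immunoglobulin segments, 60 Ighv had a median of -0.39 and 63 Igkv of -0.10. C130026I21Rik had 955 counts against 18 and A530032D15Rik, its neighbour but 1 in GRCm38 order, 1328 against 287. Gm9855 had 461 against 22 and Gm6724 274 against 0.

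The 4 genes from St6galnac2 to St6galnac1 near Srsf2 had a median difference of -2.34, the lowest of 12452 windows of 4 consecutive genes, and the lowest window sharing no gene with them was that of H2-Ob, H2-Ab1, H2-Aa and H2-Eb1 at -1.79. Chance placement is argued against by 2 of 1000 random gene orders with a window as low, though the window's size was chosen from this run. Loss of 1 of 2 equally active copies which would leave about 50%, is argued against too, since the run's pooled level was 0.176% of the WT level (upper bound 0.282%). BC018473 carries that value with 11077 of 11644 WT reads, and without it the other 3 genes were at 3.62% (2.09 to 5.84), and St6galnac2 alone at 8.42% (4.63 to 14.2). A haplotype of the region that differs between the mice on both chromosomes may account for the run and stays open along with genotype, sex and age, since there is 1 library per genotype.

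Ear10 and Ear12 together had 9 counts against 3844, a log2 ratio of -8.47. Fewer eosinophils alone is argued against, because the upper bound of that ratio, -7.542, lies below each of the other 9 eosinophil markers, of which Il5ra was the lowest at -1.44 on the same log2 CPM ratio scale. Reads placed on a near-identical family member stay open: both genes held 4.758% of the 80797 Ear reads of the WT library, too few to see on the other Ear genes, and all 5 Ear genes together were at 48.5% of the WT level. A haplotype that differs between the mice, genotype, sex and age were not tested for this pair, nor for Rprl2 and Rprl3.

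Higher neutrophil transcripts came with lower B, natural killer, T cell and erythroid transcripts. Dilution of every other lineage alike by more neutrophil RNA is argued against as the whole cause, since the mature B median lay -1.281 from the erythroid membrane median, outside the middle 95% for pairs of random lists (-0.30 to 0.12), and the medians of the 15 lists of other cell types spanned 2.00 where as many random lists spanned 0.27 to 0.68. The authors' scaling factors move all lists alike, so they cannot make or remove distances between lists, though they set which medians lie above 0. The medians of the 18 ranked cell type lists spanned 2.892 where as many random lists spanned 0.30 to 0.75. These medians were seen before, so neither the spans nor the distance between the mature B and erythroid membrane medians is a separate test. A difference of sex, age or individual mouse may account for the pattern as well as the P95H genotype, and these cannot be told apart with 1 library per genotype. A shift in cell makeup and a change of transcripts within cells are both open as hypotheses, since the marrow was not sorted.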
